A study of Mus musculus with 6 samples.

How the data were processed

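Total RNA from flash-frozen liver of ovariectomized female mice, 3 samples from SRC-2 null and 3 from wild-type animals, was labelled with biotin, per the labels, and measured on short oligonucleotide arrays. The values used are the log2 expression values that the authors deposited in their processed table, 1 column per array, with 45101 probe sets. They were made with robust multi-array average (RMA), per the submitters' processing notes. The version of RMA, the chip description it used and a genome build are not given in the sources used here. The lowest value on an array was 1.83 to 1.92 and the highest 14.5 to 14.6. RMA pools the probes of a set after background correction and quantile normalization, so values near the low end hold mostly background and folds there are compressed. Detection calls were not used here, so a low value is not read as absence.

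Groups were taken from the labels. The replicate numbers are those of the labels, and nothing says that they mark separate animals or separate RNA preparations, so p-values measure only the spread between these samples, which may be technical. No pair of arrays held identical values. Gene names came from the array platform's annotation, which can be old. Of the 45101 probe sets, 34958 had exactly 1 gene symbol, 932 had several, 9160 had none listed and 64 were controls. Of the 34958, 34754 matched a mouse reference gene table (GRCm38.p6) by gene number, and 0 symbols needed an update. Because the build behind the files is not named, the table served only for names and for which genes neighbour each other, and coordinates are not printed.

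For each of 18194 genes, the probe set with the highest mean over all 6 arrays was kept among those with exactly 1 symbol. Genes whose mean over the 6 arrays was at or above the median of all probe sets, 4.21 on the log2 scale, were tested, which left 11895. Genotypes were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with genotype as the only term, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Of the called named genes apart from Ncoa2, 34 had several probe sets above the filter. When each probe set was tested on its own, all were called for 14 of these genes, some for 14 (Igk, another kappa variable gene, Ppp1r3c, Tpi1, Thrsp, Idi1, Pltp, Srxn1, Zbtb16, Saa4, Ccnd1, Rgs5, Stau2 and Terf1) and none for 6 (Esr1, Esrra, Cdkn1a, Herpud1, Flt1 and Sparc), and for Srxn1 and Sparc they differed in direction. Fold changes are SRC-2 null against wild-type, and the median log2 fold change over all tested genes was 0.00. Probe sets whose names end in _s_at or _x_at can detect several related transcripts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

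The 35 gene lists, for liver functions, other cell types, sample handling and the neighbourhood of the targeted gene, were fixed before the data were examined, as were the test, the filter and most of the alternatives. Lists with at least 4 measured members, 33 in all, were tested with camera at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry, each with Benjamini-Hochberg adjustment over the lists. Of the 18 lists called with the preset correlation, 4 upward and 14 downward, the macrophage and the female-biased lists kept their calls with an estimated correlation. The estimate was not always above the preset 0.01. For example, it was -0.003, -0.027 and -0.065 for the acute phase, complement and coagulation, and cell cycle lists, which lost their calls too. A higher correlation is therefore not the reason for the loss in those lists. For the acute phase list the unadjusted camera p was 0.00106 with the preset and 0.0218 with the estimate. A call lost with an estimated correlation is thus not by itself a sign that correlation between genes undid it. Fry, which tests whether the genes of a list move one way on balance and compares them with no other genes, called 20. Counts of members are given over all genes tested and adjusted over the list alone. Some genes stand in more than 1 list, and some lists also hold regulators, transporters or related enzymes of the function they are named for.

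The genes named were Ncoa2, Ncoa1 and Ncoa3, the 15 higher and the 15 lower genes with the largest fold change among called genes whose groups did not overlap, and for each list up to 4 members with the smallest p. Had fewer than 10 genes passed in a direction, the genes with the smallest unadjusted p would have filled up to 10, described by value only. Genes named because a count of 5 or fewer held them are marked as named after their values were seen. Of 154 named genes 109 apart from Ncoa2 were called, and 80 of these stayed called without each array in turn.

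The procedure was tested on simulated data for the same comparison and 11895 genes, 200 of them changed. It recovered 48% of genes changed 1.5-fold, 76% of those changed 2-fold, 98% of those changed 4-fold and 100% of those changed 8-fold. It made 168 calls with 7 false ones (4.17%), and 0 calls in data without a change. The values were drawn once, gene by gene, from normal distributions, without an array batch and without correlation between genes. The real arrays have both, so these rates may not hold for them.

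Whether equal replicate numbers pair arrays was checked by correlating, across genes, the deviations of arrays from their group means. The correlations were 0.18, 0.20 and 0.52 for replicates 1, 2 and 3, which met the rule set beforehand (every pair above 0.1). The rule cannot show pairing by number, because replicates 1 and 2 met it with exchanged numbers too. Wild-type replicate 1 correlated at 0.21 with null replicate 2, and wild-type replicate 2 at 0.17 with null replicate 1. The labels state no pairing, and the structure is chiefly that of replicate 3 apart. The hybridization controls showed the same division, and a block for this array batch and a fit to replicates 1 and 2 only were added after the data were seen. The labels name no batch or date, so the array batch is inferred from the values. What sets replicate 3 apart, in the run of the arrays or in the samples, is not recorded. Other alternatives were no filter, a stricter filter at the 70th percentile, the mean of all probe sets of a gene, every probe set on its own, a trended robust variance, array weights, quantile normalization again, arrays centred on their medians, the replicate block, an adjusted p under 0.10 and each array left out in turn. Probe sets with no single symbol were left out of the comparison and tested apart.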

Results

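RNA abundance was measured in the livers of female mice with short oligonucleotide arrays, in animals lacking SRC-2 and in wild-type animals. SRC-2, the protein of Ncoa2, is a coactivator of nuclear receptors in the p160 family, which also holds the proteins of Ncoa1 and Ncoa3. The mice were on a C57 background, were ovariectomized at 6 weeks of age and were killed 2 weeks later. Each genotype had 3 arrays, and each array held log2 values for 45101 probe sets with medians between 4.17 and 4.24. The comparison asks which hepatic transcripts differ when SRC-2 is missing. The number of arrays limits the precision of every value. After the removal of dim genes, 11895 genes were tested.

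Ncoa2 itself was lower in the SRC-2 null livers. Its brightest probe set, 1435233_at, had a mean of 8.07 ± 0.41 (SD, n = 3) in wild-type and 5.63 ± 0.21 (SD, n = 3) in null liver, a 5.41-fold lower level (log2 fold change -2.44, SE 0.20, limma adjusted p = 0.000354). The 3 wild-type arrays read 7.74, 7.92 and 8.53, and the 3 null arrays read 5.60, 5.44 and 5.86. A second probe set, 1435234_at, fell from 6.36 ± 0.21 to 4.19 ± 0.13, with an adjusted p of 0.000119 among all single-gene probe sets. The other 2 Ncoa2 probe sets, 1446827_at and 1450458_at, had log2 fold changes of 0.07 and -0.27 and did not pass the test. The labels do not describe the allele, so a probe set outside the deleted part checks nothing. The related coactivator genes did not pass the test, with log2 fold changes of -0.13 for Ncoa1 (adjusted p = 0.538) and -0.27 for Ncoa3 (adjusted p = 0.313).

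**Figure D1:**
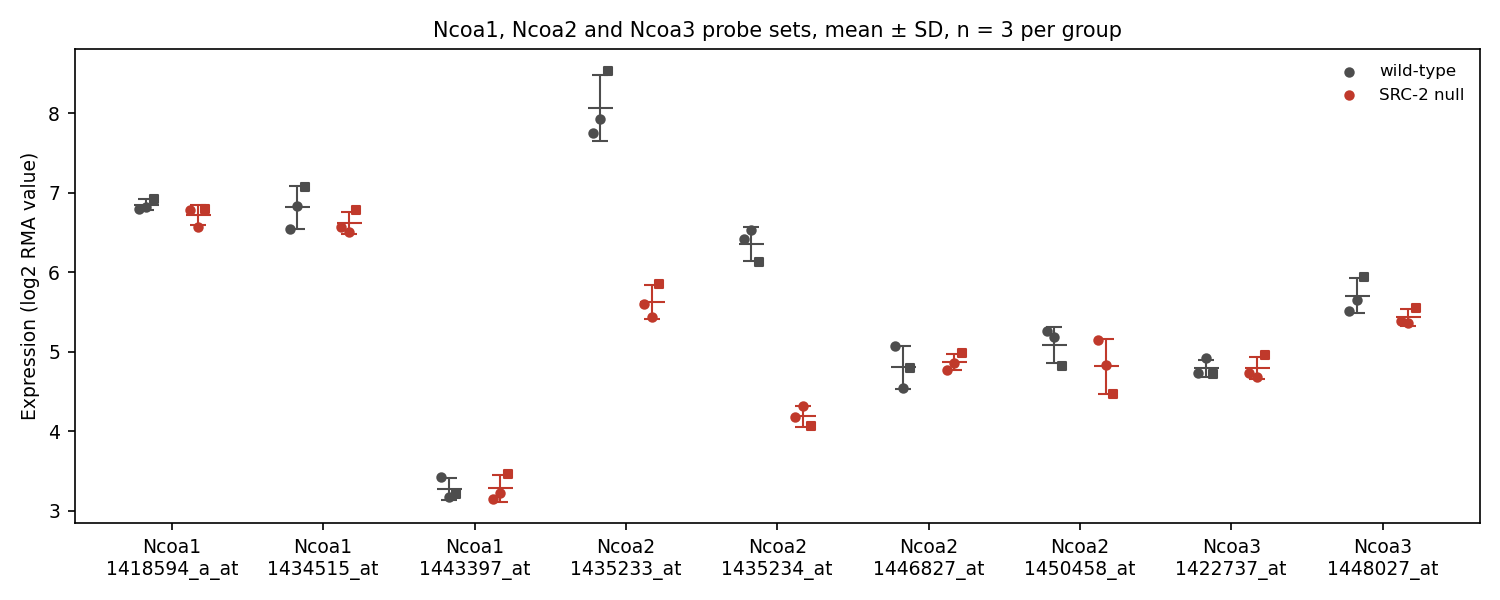
Expression of each probe set of Ncoa1, Ncoa2 and Ncoa3 on the 6 arrays (vertical axis, log2 RMA value), with points for single arrays, squares for replicate 3, and horizontal marks with error bars for the mean ± SD of 3 arrays. The wild-type and SRC-2 null arrays separate at 1435233_at and 1435234_at of Ncoa2, with log2 fold changes of -2.44 and -2.16.

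In SRC-2 null liver, 16 of 17 macrophage markers, 3 of 6 B and plasma cell markers, 9 of 16 immediate early genes and 8 of 20 female-biased genes were lower. Of 16 lipid droplet and lipid uptake genes 6 were higher and 2 lower, and of 14 male-biased genes 6 were higher and 1 lower. All 6 lists passed the camera test, but with an estimated correlation the macrophage and female-biased lists alone of these kept their calls, and the adjusted p was 0.125 for the B and plasma cell, 0.127 for the immediate early, 0.185 for the lipid and 0.327 for the male-biased list. In all, 556 genes differed between the genotypes, 4.67% of those tested, with 184 higher and 372 lower in null liver. Of these, 313 differed at least 1.5-fold, 81 higher and 232 lower. The number of genes changed was 329, 275, 301 and 294 without wild-type replicate 1, wild-type replicate 2, null replicate 1 and null replicate 2. The number of genes higher in SRC-2 null was 71, 65, 82, 77 and 101 without these arrays in turn and without null replicate 3, and that of genes lower in SRC-2 null was 210, 219 and 217 without wild-type replicate 2, null replicate 1 and null replicate 2. Aqp4, a water channel, rose 6.98-fold (log2 fold change 2.80, SE 0.12, adjusted p = 9.67e-06). Cidec, a lipid droplet protein, rose 6.25-fold from 3.50 ± 0.13 to 6.14 ± 0.01 (SD, n = 3). Apoa4, an apolipoprotein, rose 3.75-fold, and Fabp4, a fatty acid-binding protein of adipocytes and macrophages, rose 3.31-fold. The acetyltransferase gene Nat8 rose 2.96-fold, Lrtm2 3.20-fold and Bhlhb9 2.62-fold. Krt23, a keratin, Omd, a matrix proteoglycan, and Gal3st1, a sulfotransferase of glycolipids, rose 2.54-fold, 2.53-fold and 2.44-fold. The trehalase gene Treh rose 2.39-fold, but its call (adjusted p = 0.0299) was lost when any wild-type array or null replicate 2 was left out. Aqp4, Cidec, Cidea, Ugt2b38, Lrtm2 and Treh had wild-type means below 4.21, the value that set the filter on dim genes, and a fold against so low a value can be understated, so the order of these rises is uncertain.

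Among the lower transcripts, Dmbt1, a secreted scavenger receptor protein, fell from 7.15 ± 0.19 to 3.15 ± 0.16 (SD, n = 3), a 15.9-fold difference (log2 fold change -3.99, SE 0.12, adjusted p = 3.15e-06). The immunoglobulin genes Ighm, Igk and Igkv8-30 fell 11.7-fold, 9.98-fold and 9.01-fold, and another kappa variable gene fell 6.42-fold. Igk and this last gene each had a further probe set that was not called, with log2 fold changes of -0.68 and -0.19. The null levels of Dmbt1, Igk, this kappa variable gene, Cnmd, Timd4 and Nkg7 lay below 4.21, the value that set the filter, so their falls can be understated too. Immunoglobulin genes resemble each other closely, so the identity of each such probe set is uncertain. Rgs16, a regulator of G protein signalling, fell 4.63-fold, Cnmd, the chondromodulin gene, 4.52-fold, Serpina7, which encodes thyroxine-binding globulin, 4.29-fold, and 9030619P08Rik 6.80-fold. Cd74, the invariant chain of class II antigen presentation, fell 4.16-fold. Across all tested genes, 2781 (23.4%) had values on the 3 null arrays that did not overlap those on the 3 wild-type arrays. The share by chance is 10% if the 6 arrays were exchangeable, which leaves out that replicate 3 of both genotypes stands apart.

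Markers of Kupffer cells and macrophages, the resident phagocytes of the liver, fell almost throughout. Of 17 measured, 16 fell and none rose (0 at an unadjusted p under 0.05 in limma), and 17 fell when adjusted over the list alone. The median log2 fold change was -0.94, with medians of -0.96 within replicates 1 and 2 and -0.999 within replicate 3. Marco, a scavenger receptor, fell 5.10-fold from 8.37 ± 0.10 to 6.02 ± 0.05 (SD, n = 3). Timd4, Cd5l and C1qb, which encode a phosphatidylserine receptor, a secreted scavenger receptor protein and a complement subunit, fell 2.63-fold (to a null level of 4.18, below the filter value), 2.22-fold and 2.21-fold. The remaining marker, Fcgr1, had a log2 fold change of -0.92, with a null level of 4.04, and did not pass (adjusted p = 0.0825); it was named after its value was seen. The list passed the camera test (adjusted p = 1.2e-27) and kept its call at an adjusted p of 0.0105 with an estimated correlation. With the array batch block as well, the adjusted p with an estimated correlation was 0.056.

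Transcripts of other leukocytes were lower in part, beside that fall of the macrophage markers. Of 6 B and plasma cell markers, 3 fell and none rose (0 at an unadjusted p under 0.05 in limma), and 5 fell when adjusted over the list alone, with a median log2 fold change of -0.996. These were Ighm, Jchain, which joins antibody chains into polymers and fell 5.69-fold, and Mzb1, an antibody-secretion factor that fell 2.59-fold. The list passed (camera adjusted p = 5.24e-09), but not with an estimated correlation, where the adjusted p was 0.125. Of 9 T and NK cell markers, the chemokine gene Ccl5 (2.07-fold) and the granule protein gene Nkg7 (1.72-fold, to 4.04) fell, and 7 did not pass (5 fell when adjusted over the list alone). The median was -0.37 with a camera adjusted p of 0.000171, and the call was lost at an adjusted p of 0.184 with an estimated correlation. None of 7 neutrophil markers passed in limma, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.788 in camera and 0.817 in fry).

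Genes of the other cell types of liver did not shift as lists. Of 17 endothelial markers 1 rose, the receptor gene Flt1 (log2 fold change 0.44, adjusted p = 0.0431), a call that was lost whichever array was left out, and 2 rose when adjusted over the list alone. The median of the endothelial list was 0.01 and its camera adjusted p was 0.429. Of 19 stellate cell and matrix genes, Rgs5 rose 1.57-fold and Sparc 1.31-fold (2 rose and 1 fell when adjusted over the list alone, list adjusted p = 0.557). With the mean of all probe sets of a gene both lost their calls, 1 of the 4 probe sets of Rgs5 being called when each was tested, and Sparc also lost its call whichever array was left out. Of 8 cholangiocyte markers, Krt23 rose while Cd24a (2.00-fold) and Krt19 (1.40-fold) fell, with 1 higher and 3 lower when adjusted over the list alone. The list's adjusted p was 0.87, with a median of 0.09 and mean of 0.01 above 0 and the test direction down. Krt19 lost its call without wild-type replicate 2 or null replicate 1. None of 6 exocrine pancreas genes passed in limma, and 1 had an unadjusted p under 0.05 (list adjusted p = 0.485 in camera and 0.458 in fry). Too few adipocyte and erythroid markers were bright enough for a list test. Fabp4 rose, and Retn, a resistin gene, had a log2 fold change of 0.30 and did not pass. Alas2, an enzyme of haem synthesis in red cells, rose 1.55-fold, and the red cell anion exchanger gene Slc4a1 had a log2 fold change of 0.07 and did not pass. Adjusted over the list alone, 2 of the 2 adipocyte and 1 of the 2 erythroid markers rose.

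**Figure D2:**
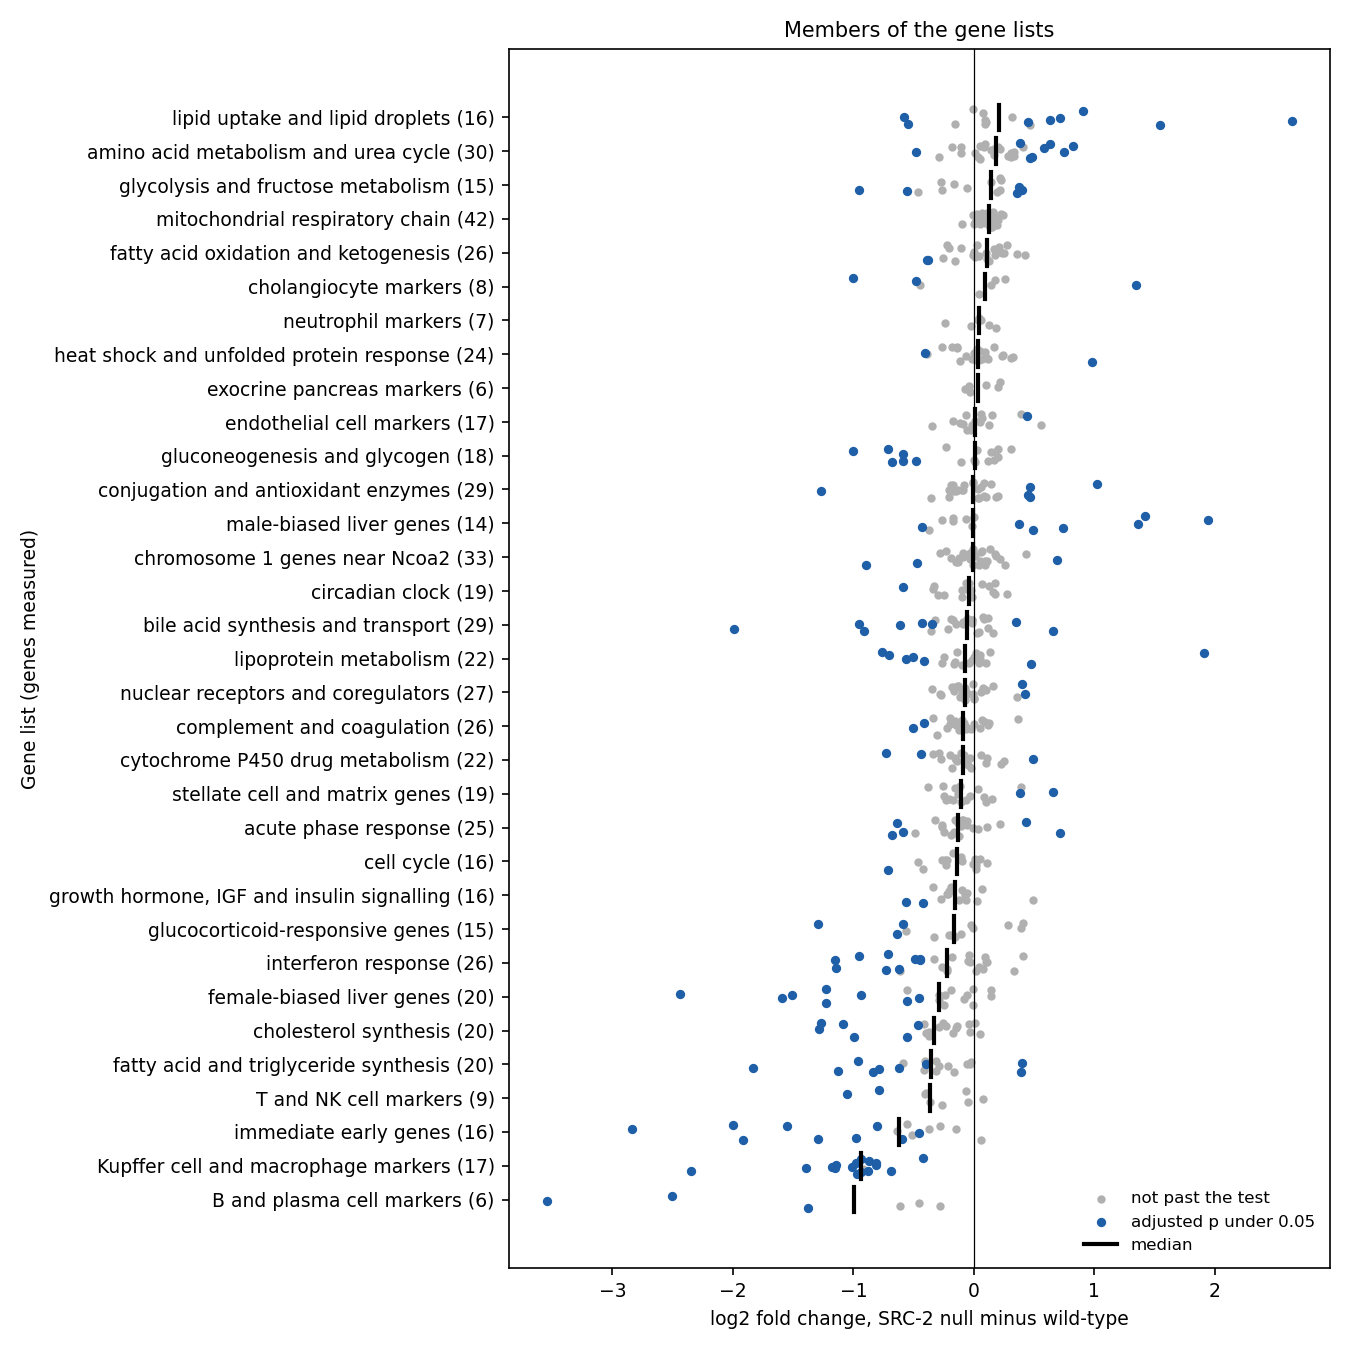
Log2 fold change, SRC-2 null minus wild-type (horizontal axis), of the measured members of each gene list with at least 4 of them (vertical axis, number measured in parentheses). Each point is 1 gene, blue where its adjusted p was under 0.05, and black bars are list medians. The macrophage markers lie wholly to the left of 0, with a median of -0.94, and the endothelial markers lie around 0, with a median of 0.01.

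Of 16 immediate early genes, which are switched on within minutes by many stimuli, 9 fell, 7 did not pass and none rose (0 at an unadjusted p under 0.05 in limma), and 12 fell when adjusted over the list alone. The median log2 fold change was -0.62 with a camera adjusted p of 1.71e-15, and the call was lost at an adjusted p of 0.127 with an estimated correlation. Fos and Jun, subunits of the AP-1 transcription factor, fell 7.14-fold and 3.99-fold, Fos from 8.66 ± 0.06 to 5.83 ± 0.14 (SD, n = 3). Gadd45g, a stress-induced gene, fell 2.92-fold, and the phosphatase gene Dusp1 2.45-fold. Macrophage markers moved the same way, with a median of -0.94. Of 15 glucocorticoid-responsive genes, 3 fell, namely Dusp1, Zbtb16 (1.56-fold), a transcriptional repressor, and Cdkn1a (log2 fold change -0.59), a cell cycle inhibitor, and 1 rose and 4 fell when adjusted over the list alone. Zbtb16 and Cdkn1a lost their calls without wild-type replicate 1, null replicate 1 or null replicate 2, and Cdkn1a also without either of the other wild-type arrays. This list had a median of -0.17 and an adjusted p of 0.0168, which became an adjusted p of 0.131 with an estimated correlation, 0.0574 without null replicate 3 and 0.0738 in replicates 1 and 2 only.

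Of 26 interferon-responsive genes, 9 fell, 17 did not pass and none rose (2 at an unadjusted p under 0.05 in limma), and 12 fell and 1 rose when adjusted over the list alone, beside the fall of the macrophage markers (median -0.94). The median log2 fold change was -0.23 with a camera adjusted p of 3.56e-05, and the call was lost at an adjusted p of 0.131 with an estimated correlation. The GTPase genes Igtp and Gbp2 fell 2.22-fold and 2.21-fold, Bst2, an antiviral membrane protein, 1.64-fold and the transcription factor gene Irf7 1.54-fold. Among 25 acute phase genes the serum amyloid A genes moved apart: Saa2 and Saa1 rose 1.64-fold and 1.35-fold, and Saa4 fell 1.60-fold. Apcs, the serum amyloid P gene, and Orm3 fell, with log2 fold changes of -0.64 and -0.58, and Orm3 lost its call without wild-type replicate 1, wild-type replicate 2 or null replicate 1. Saa1 was named after its value was seen, and its probe set can also detect close relatives. Adjusted over the list alone, 2 rose and 8 fell. The median was -0.13, the adjusted p was 0.0029, and the adjusted p was 0.125 with an estimated correlation. Of 26 complement and coagulation genes, the mannose-binding lectin genes Mbl1 and Mbl2 fell 1.42-fold and 1.33-fold (1 higher and 2 lower when adjusted over the list alone), and the list median was -0.09. Mbl1 lost its call without wild-type replicate 2 or null replicate 2, and Mbl2 without any array but wild-type replicate 3. The list's adjusted p of 0.017 was 0.0729, 0.0632 and 0.102 without wild-type replicate 1, wild-type replicate 2 and null replicate 3, and 0.131 was the adjusted p with an estimated correlation.

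Among 20 genes of fatty acid and triglyceride synthesis, 7 fell, 2 rose and 11 did not pass, or 14 fell and 2 rose when adjusted over the list alone. The median log2 fold change was -0.36 with a camera adjusted p of 1.98e-09, and the call was lost at an adjusted p of 0.131 with an estimated correlation. Thrsp, a regulator of lipogenesis, fell 3.56-fold from 10.21 ± 0.07 to 8.38 ± 0.08 (SD, n = 3), while 1 of its 3 probe sets had a log2 fold change of -0.02 and was not called. Lpin1, a phosphatidate phosphatase, fell 2.18-fold, Srebf1, which encodes the transcription factor SREBP-1, 1.95-fold, and Fasn, fatty acid synthase, 1.78-fold. The 2 that rose, named after their values were seen, were Elovl5, a fatty acid elongase, and Dgat1, an enzyme of triglyceride synthesis, at 1.31-fold and 1.32-fold. Of 20 genes of cholesterol synthesis, 6 fell, 14 did not pass and none rose (0 at an unadjusted p under 0.05 in limma), and 9 fell when adjusted over the list alone. The median was -0.33 with a camera adjusted p of 1.98e-09, and this call was lost too, at an adjusted p of 0.125 with an estimated correlation. Cyp51, Idi1, Fdps and Nsdhl, enzymes of the sterol pathway, fell 2.44-fold, 2.42-fold, 2.12-fold and 1.99-fold. The feeding state of the animals, which bears on genes of lipid synthesis, is not in the labels. It cannot be told apart from genotype for these lists.

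Lipid droplet and lipid uptake genes were mixed. Of 16 measured, 6 rose and 2 fell, or 8 and 2 when adjusted over the list alone, with a median log2 fold change of 0.21. Cidec and Cidea, which promote the fusion of lipid droplets, rose 6.25-fold and 2.91-fold, Lpl, lipoprotein lipase, 1.87-fold, and Fitm1, a protein of lipid droplet formation, 1.55-fold. The 2 that fell, named after their values were seen, were the droplet coat genes Plin5 and Plin4, at 1.49-fold and 1.46-fold. The camera adjusted p was 6.23e-05, and 0.185 was the adjusted p with an estimated correlation. The 2 adipocyte markers measured, Fabp4 and Retn, moved the same way, with a median of 1.01, a 3.31-fold rise of Fabp4, and 2 of 2 higher when adjusted over the list alone. Over all genes Retn did not pass (limma adjusted p = 0.242). The adipocyte genes Adipoq and Lep lay below the filter and were not tested. Cidec, Cidea and Lpl are themselves abundant in adipocytes, but so is Plin4, which fell. Whether adipocytes were in the samples was not tested. Of 22 lipoprotein genes, Apoa4 and Apoc2 (1.39-fold) rose and 5 fell, with the same counts when adjusted over the list alone. These were the sterol exporter genes Abcg5 (1.69-fold) and Abcg8 (1.63-fold), Scarb1 (1.47-fold), the high-density lipoprotein receptor, Pltp (1.42-fold), a phospholipid transfer protein, and Apom (1.33-fold), an apolipoprotein. Apoc2, Scarb1 and Apom were named after their values were seen, and Pltp lost its call without wild-type replicate 2, null replicate 1 or null replicate 2. The lipoprotein list did not pass (adjusted p = 0.126 in camera and 0.669 in fry). The list of 26 genes of fatty acid oxidation and ketogenesis did not pass in camera (adjusted p = 0.231) but did in fry, upward (adjusted p = 0.0163), with log2 fold changes above 0 for 17 of 26. In it Acot1, a thioesterase, and Angptl4, an inhibitor of lipoprotein lipase, fell 1.30-fold and 1.31-fold, and 2 rose and 2 fell when adjusted over the list alone. Acot1 lost its call whichever array was left out, and Angptl4 unless it was null replicate 3.

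Bile acid genes were mixed. Of 29 measured, 6 fell and 2 rose, or 8 and 2 when adjusted over the list alone. Cyp2c70, which makes muricholic acid in mice, fell 3.97-fold from 11.72 ± 0.08 to 9.73 ± 0.08 (SD, n = 3). Nr0b2, which encodes the repressor SHP, fell 1.93-fold, Abcb11, the bile salt export pump, 1.88-fold and Cyp27a1, a sterol hydroxylase, 1.53-fold. The 2 that rose, named after their values were seen, were Cyp8b1, the sterol 12-hydroxylase, at 1.58-fold and the transporter gene Slco1a4 at 1.28-fold. The median of the list was -0.05 with a camera adjusted p of 0.00939. That became an adjusted p of 0.131 with an estimated correlation, 0.0913 without null replicate 3 and 0.0738 in replicates 1 and 2 only.

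Some genes of glucose output and glycogen storage fell, and feeding state, which is not in the labels, cannot be told apart from genotype for them either. Of 18 measured, 6 fell and none rose (1 at an unadjusted p under 0.05 in limma), with the same counts when adjusted over the list alone. Ppp1r3g and Ppp1r3c, which target a phosphatase to glycogen, fell 2.01-fold and 1.60-fold, G6pc, the catalytic subunit of glucose-6-phosphatase, 1.64-fold, and Slc2a2, the glucose transporter GLUT2, 1.40-fold. G6pc went from 10.96 ± 0.05 to 10.25 ± 0.04 (SD, n = 3), and Slc2a2 lost its call without wild-type replicate 2, and Ppp1r3c with the mean of its 2 probe sets. The list did not pass in camera (adjusted p = 0.0722) but did in fry, downward (adjusted p = 0.000704), and its median of 0.01 and mean of -0.17 differed in sign, the test direction being down. It passed in camera at an adjusted p of 0.038 without wild-type replicate 3, 0.0264 with no filter and 0.0344 with the mean of all probe sets of a gene. Of 15 genes of glycolysis and fructose metabolism, Ldha, Tpi1 and Pgam1 rose 1.32-fold, 1.30-fold and 1.28-fold, while Pdk4, a kinase that inhibits pyruvate dehydrogenase, and Khk, ketohexokinase, fell 1.94-fold and 1.47-fold. Pgam1 was named after its value was seen. Ldha and Tpi1 lost their calls whichever array was left out, and Khk unless it was null replicate 3. Adjusted over the list alone, 4 rose and 4 fell. That list did not pass (adjusted p = 0.636, and 0.0453 with the stricter filter, where it passed), and its mean of -0.04 lay below 0 while its median of 0.14 lay above.

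Among 30 genes of amino acid metabolism and the urea cycle, 7 rose, 1 fell and 22 did not pass, or 13 rose and 2 fell when adjusted over the list alone. The median log2 fold change was 0.19 with a camera adjusted p of 1.12e-06, and the call was lost at an adjusted p of 0.125 with an estimated correlation. Agxt, which detoxifies glyoxylate, rose 1.77-fold from 10.59 ± 0.03 to 11.42 ± 0.08 (SD, n = 3). Asl, argininosuccinate lyase, rose 1.68-fold, Hal, histidine ammonia-lyase, 1.55-fold, and Aass, an enzyme of lysine breakdown, rose with a log2 fold change of 0.59. The 1 that fell, named after its value was seen, was Glul, glutamine synthetase, at 1.40-fold. The mitochondrial respiratory chain list passed as well (adjusted p = 0.000125), with an adjusted p of 0.323 with an estimated correlation and 0.0952 in fry. Its shift was small, with a median of 0.13, log2 fold changes above 0 for 40 of 42 genes, none past the test in limma (0 also when adjusted over the list alone) and 3 at an unadjusted p under 0.05.

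Of 20 female-biased liver genes, which are expressed more in female than in male mouse liver, 8 fell, 12 did not pass and none rose (0 at an unadjusted p under 0.05 in limma), and 11 fell when adjusted over the list alone, with a median log2 fold change of -0.29. The sulfotransferase genes Sult2a2 and Sult3a1 fell 5.42-fold and 2.84-fold, Sult2a2 from 11.37 ± 0.00 to 8.93 ± 0.09 (SD, n = 3). Cyp17a1, a steroid hydroxylase, and Acot3, a thioesterase, fell 2.35-fold and 2.34-fold. The list passed with a camera adjusted p of 1.04e-09 and an adjusted p of 0.0348 with an estimated correlation, which became 0.127 with the array batch block as well. Of 14 male-biased genes, 6 rose and 1 fell, or 6 and 2 when adjusted over the list alone. Cyp4a12a, a fatty acid hydroxylase, rose 3.85-fold from 6.41 ± 0.11 to 8.35 ± 0.08 (SD, n = 3). Ugt2b38, a glucuronosyltransferase, rose 2.68-fold, Cyp2d9, a steroid hydroxylase, 2.57-fold and Susd4, a complement regulator, 1.67-fold. The 1 that fell, named after its value was seen, was Ugt2b1, another glucuronosyltransferase, at 1.35-fold. The median of the male-biased list was -0.01 while its mean was 0.35, and its camera adjusted p of 0.0188 in the upward direction was lost at 0.0928 with the stricter filter, 0.103 with the replicate block, 0.0834 with the array batch block, 0.0738 in replicates 1 and 2 only and an adjusted p of 0.327 with an estimated correlation. Several of these enzymes have close relatives in the mouse that their probe sets may not tell apart.

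**Figure D3:**
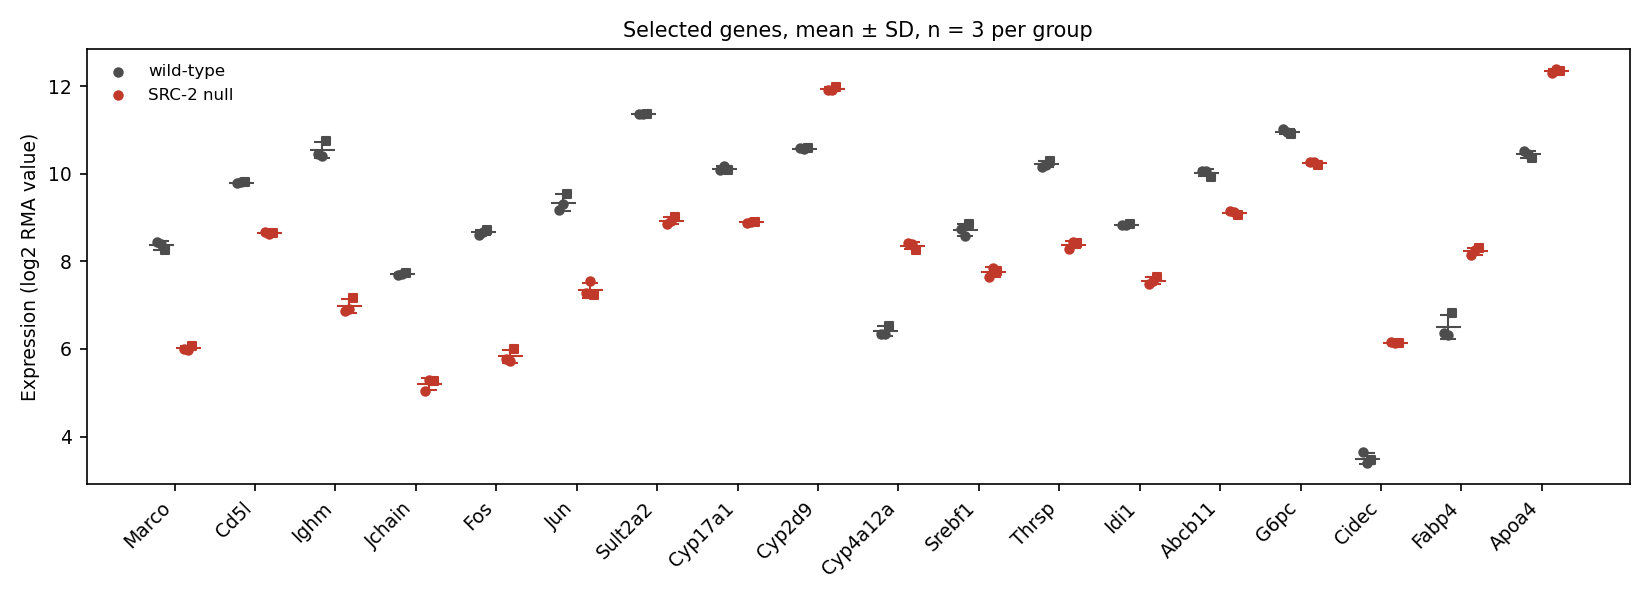
Expression (vertical axis, log2 RMA value) of 18 named genes on the 6 arrays, with points for single arrays, squares for replicate 3, and marks with error bars for the mean ± SD of 3 arrays. In each gene the 3 null arrays do not overlap the 3 wild-type arrays, as for Sult2a2, whose means are 11.37 and 8.93.

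Drug-metabolizing enzymes were mixed. Of 22 genes of drug metabolism, mostly cytochrome P450 genes and their regulators but also the carboxylesterase gene Ces2a and the aldehyde dehydrogenase gene Aldh1a1, Ces2a rose 1.41-fold, and Cyp1a2 and Cyp2c37 fell 1.66-fold and 1.35-fold (1 higher and 4 lower when adjusted over the list alone). Cyp1a2 lost its call without null replicate 1 or null replicate 2, Ces2a whichever array was left out, and Cyp2c37 unless it was null replicate 3. Of the 22, 16 had log2 fold changes below 0, and fry called the list downward (adjusted p = 0.0495). Its camera adjusted p of 0.0756 did not pass, and became 0.0302 without wild-type replicate 3, 0.00933 without null replicate 1, 0.0444 with no filter, 0.0301 with a trended robust variance and 0.0409 with array weights, where it passed. Of 29 conjugation and antioxidant genes, 4 rose and 1 fell, or 4 and 2 when adjusted over the list alone (list adjusted p = 0.87, with a median just below 0, a mean just above and the test direction up). The glutathione transferase gene Gstm3 fell 2.40-fold while Gsta2 rose 2.03-fold. Srxn1 and Nqo1, known targets of the antioxidant response, rose 1.38-fold and 1.37-fold, each lost without any of 4 single arrays. Srxn1 was also lost with the mean of all its probe sets, of which 1 of 4 was called and 1 had a log2 fold change below 0 (-0.03), and Gstt2, named after its value was seen, rose 1.38-fold.

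Growth hormone, IGF and insulin signalling genes had a median log2 fold change of -0.16. Of 16 measured, Irs1, an insulin receptor substrate, and Igfals, a carrier of IGF, fell 1.48-fold and 1.34-fold (the same 2 counted when adjusted over the list alone), each lost unless null replicate 3 was the array left out. The list's adjusted p was 0.0102, with an adjusted p of 0.184 with an estimated correlation and 0.0738 in replicates 1 and 2 only. Of 27 nuclear receptors and coregulators, Esr1 and Esrra rose 1.34-fold and 1.32-fold, both lost whichever array was left out (list adjusted p = 0.636, with 2 higher when adjusted over the list alone). Of 19 circadian clock genes, 1 fell, the repressor gene Bhlhe40, at 1.51-fold (list adjusted p = 0.429, with 1 lower when adjusted over the list alone). Of 16 cell cycle genes, 1 fell, the cyclin gene Ccnd1, at 1.64-fold, also when adjusted over the list alone. The cell cycle list had a median of -0.14 and an adjusted p of 0.0181, which became 0.0943 with the stricter filter, 0.0517 without wild-type replicate 1, 0.0909 without null replicate 3 and an adjusted p of 0.131 with an estimated correlation. Of 24 heat shock and unfolded protein response genes, Asns, asparagine synthetase, rose 1.97-fold and Herpud1, a protein of endoplasmic reticulum quality control, fell 1.32-fold (2 higher and 2 lower when adjusted over the list alone, list adjusted p = 0.63). Asns lost its call without null replicate 1, and Herpud1 whichever array was left out.

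Of the genes near Ncoa2 on chromosome 1, fixed as a list because a targeted allele can carry linked sequence from another strain, 3 of 33 tested changed. This share of 9.09% did not pass against the 4.67% of all tested genes (Fisher's exact test, two-sided, p = 0.198). Stau2, which encodes an RNA-binding protein, rose 1.62-fold, while Terf1, a telomere-binding factor, and Snhg6, a small nucleolar RNA host gene, fell 1.86-fold and 1.39-fold. The counts when adjusted over the list alone were 1 higher and 2 lower, and the list's camera adjusted p was 0.87, with a median and mean just below 0 and the test direction up. Without wild-type replicate 1, and likewise without wild-type replicate 2, 1 of the 33 was called. Terf1 lost its call without wild-type replicate 1 or wild-type replicate 2, and Snhg6 unless null replicate 3 was the array left out. In replicates 1 and 2 only, all 3 lost their calls.

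Spiked-in hybridization controls divided the arrays otherwise than by genotype. Their mean over 9 probe sets lay between 10.66 and 10.91 on replicates 1 and 2 of both genotypes, and was 9.18 and 9.23 on wild-type and null replicate 3. The difference between the 3′ and 5′ probe sets of pyruvate carboxylase was 2.15 to 2.29 on the arrays of replicates 1 and 2, and 3.20 and 3.30 on those of replicate 3. The labels name no batch, and RNA quality of replicate 3 was not tested as a source of this division. With this inferred array batch as a block, 983 genes passed (376 higher and 607 lower), including 555 of the 556. With the replicate number as a block 832 passed, 307 of them higher. Within replicates 1 and 2 alone 329 genes passed, and 325 of these (98.8%) had the same direction in the replicate 3 pair, which has 1 array per genotype and no test of its own. Across genes, which are not independent replicates, the fold changes of the batches correlated at r = 0.705.

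**Figure D4:**
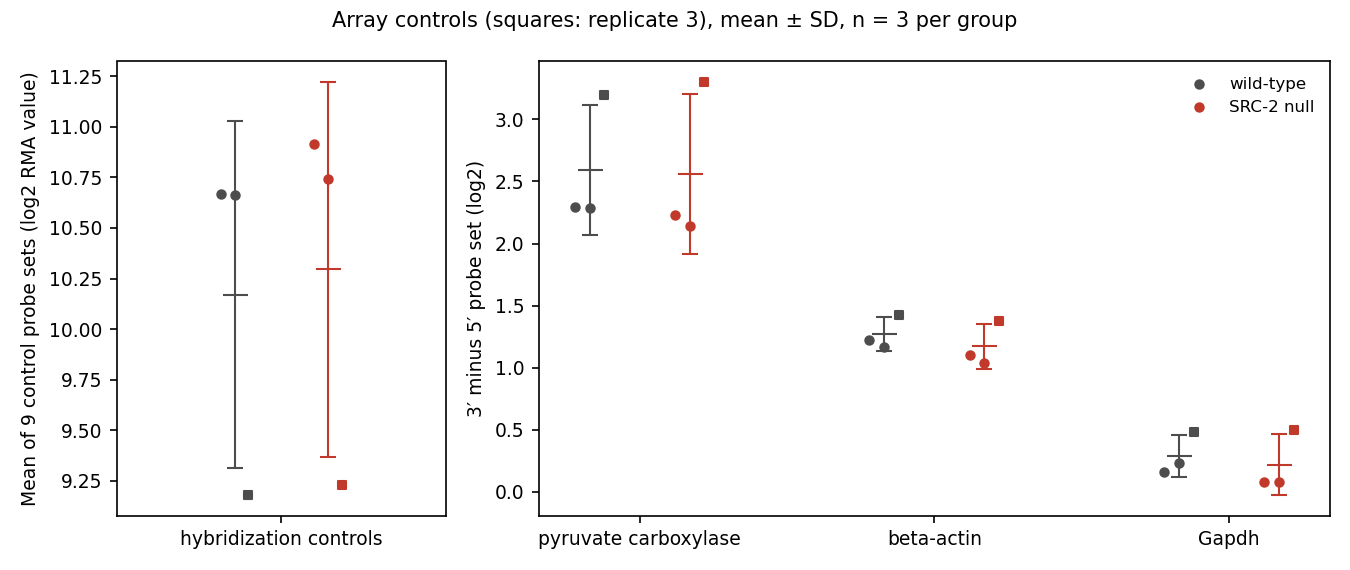
Left, mean of the 9 hybridization control probe sets on each array (log2 RMA value), and right, difference between the 3′ and 5′ probe sets of pyruvate carboxylase, beta-actin and Gapdh (log2), with points for single arrays, squares for replicate 3, and marks with error bars for the mean ± SD of 3 arrays. The replicate 3 arrays of both genotypes lie apart, at 9.18 and 9.23 for the hybridization controls against 10.66 to 10.91 for the other 4 arrays.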

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

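Among 2892 probe sets above the filter that carry no gene symbol or several, and so stand outside the comparison of genes, 64 differed between the genotypes (limma adjusted p under 0.05), 14 higher and 50 lower in SRC-2 null liver, and 19 of the 64 carry several symbols. They are given here because a signal above the wild-type level appeared in data that the comparison of genes did not use. The probe set 1417867_at rose from 3.81 to 6.52 (log2 fold change 2.71, SE 0.25, adjusted p = 0.000591), and 1441430_at rose from 7.71 to 9.01 (log2 fold change 1.30, adjusted p = 0.000123). The probe set 1424631_a_at fell from 8.32 to 4.91 (log2 fold change -3.41, adjusted p = 7.94e-06), and 1426174_s_at fell from 7.07 to 4.09 (log2 fold change -2.98, adjusted p = 2.05e-05).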

How the results depend on the processing

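The array batch block, its combination with an estimated correlation and the fit to replicates 1 and 2 only were chosen after the data were seen, and the other settings before. Ncoa2 stayed lower and called, with log2 fold changes between -2.60 and -2.20 without each array in turn. Without each array in turn, the number of genes changed was 275 to 438 (556 with all arrays), of genes higher in SRC-2 null 65 to 174 (184), of genes lower in SRC-2 null 210 to 315 (372) and of genes changed at least 1.5-fold 258 to 327 (313), with 14 to 20 lists called (18) and 1 to 3 genes near Ncoa2 (3). Fewer arrays enter these fits. With array weights 985 genes changed, 405 higher and 580 lower, and at an adjusted p under 0.10, a looser threshold, 839 changed and 316 were higher. With every probe set tested on its own, 121 were higher. The replicate block, which treats equal replicate numbers as pairs, gave 832 changed genes, 307 of them higher, and kept 549 of the 556. It ended the call of the male-biased list (adjusted p = 0.103) and no other call of a list or named gene. The array batch block gave 983, with 376 higher and 607 lower, and replicates 1 and 2 only gave 329, with 95 higher and 234 lower, from 4 arrays. Nat8, Bhlhe40, Ppp1r3c, Fitm1, Ccnd1, Alas2 and Stau2, which stayed called without each array in turn, lost their calls in that fit. With the mean of all probe sets, Ppp1r3c, Srxn1, Esr1, Esrra, Cdkn1a, Flt1, Rgs5 and Sparc lost their calls. Of the genes near Ncoa2, 1 passed with the stricter filter and 1 with the mean of all probe sets, Snhg6 in both, where Stau2 and Terf1 fell below the filter and were not tested. In replicates 1 and 2 only 1 passed, Lactb2, named after its value was seen, and none of the 3 called with all arrays (adjusted p 0.0689, 0.124 and 0.0728 for Stau2, Terf1 and Snhg6). With an estimated correlation 2 lists were called by camera, and with the array batch block as well 0, where 9 had an unadjusted p under 0.05. Fry called 20 lists, and camera with either block 17. Apart from the fits with fewer arrays, the genes left untested and the looser threshold, the cause of these shifts was not tested. Among named genes 7 values, none of a called gene, changed sign. Without each array in turn the level of Mpo ranged from -0.041 to 0.328, the level of S100a9 from -0.0082 to 0.123, the level of Cela3b from -0.212 to 0.0387 and the level of Slc4a1 from -0.0013 to 0.160. The level of S100a9 was -0.046 in replicates 1 and 2 only, and the level of Ctrb1 -0.047 with array weights. The cause was not tested. Over all settings, 2403 of 2700 values of named genes kept direction and call, 196 lost a call, 94 gained one and 7 changed sign, and of 555 values of lists 529 kept theirs, 15 lost a call and 11 gained one. Signal over background limits the dim genes, whose folds RMA compresses.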

Other observations

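Gene groups chosen after the values were seen extend the account of leukocyte transcripts. Of 8 genes of MHC class II antigen presentation, 5 fell, with a median log2 fold change of -1.24 (-1.23 within replicates 1 and 2, -1.26 within replicate 3). Cd74, the invariant chain, fell from 9.61 to 7.55, H2-Aa from 9.51 to 7.49, H2-Ab1 from 7.93 to 6.15 and H2-Eb1 from 8.19 to 6.53. The class II transactivator gene Ciita had a log2 fold change of 0.01 at a level of 4.24 and did not pass. Of 6 MHC class I genes, none passed in limma and 3 had an unadjusted p under 0.05, with a median of -0.16. Of 14 genes of leukocyte integrins, Fc receptors and other leukocyte surface or lysosomal proteins, 12 fell, with a median of -0.96. Among them the pan-leukocyte gene Ptprc had a log2 fold change of -1.04 (adjusted p = 0.00431), the integrin gene Itgb2 -1.36 (adjusted p = 0.00146) and the Fc receptor gene Fcgr4 -1.65 (adjusted p = 0.00632).

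Of 11 immunoglobulin genes, 7 fell and 1 rose, with a median log2 fold change of -1.74. The 1 that rose, a kappa variable gene, had a log2 fold change of 1.20 (adjusted p = 0.000952) from a level of 4.25, while Igha, the heavy chain of immunoglobulin A, had -1.55 and Iglv1 -1.74. Called genes also stood together along chromosomes. Among 585 runs of 20 tested genes, a run on chromosome 3 with genes of the Adh and Gbp families and a run on chromosome 7 with Saa4, Saa1, Saa2, Ldha, Csrp3, Gm2788 and Nav2 held 7 called genes each (binomial test, adjusted p = 0.00644 each), and a run on chromosome 6 with immunoglobulin kappa genes held 6 (binomial test, adjusted p = 0.0446). Members of gene families lie next to each other in these runs, and probe sets of such genes can detect each other's transcripts. The binomial test takes the genes of a run as independent, so these p-values can be too small. In the chromosome 7 run Ldha, Csrp3, Gm2788 and Nav2 are not Saa genes. Among the 10, 20 and 40 tested genes nearest to Ncoa2 by order, 1, 3 and 3 were called, and none of these shares passed (Fisher's exact test, two-sided, p = 0.38, 0.0638 and 0.434). Between replicates 1 and 2 of a genotype, 41 immediate early and acute phase genes differed by a median of 0.06 on the log2 scale, against a median of 0.08 over 10000 random lists of the same level, which is percentile 4.02.

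The tests in the next 3 paragraphs were chosen after the results were seen, and the splits of the arrays before. For the first pattern, the fall of macrophage markers, a larger share of hepatocyte RNA would lower every other cell type alike, but the endothelial median was 0.0119 while the 75th percentile of the macrophage markers was -0.871. The array batch does not account for it either, because each batch holds equal numbers of arrays of both genotypes. The medians were -0.955 and -0.999 within the 2 batches. Fewer macrophages, or the loss of a subset of them, may be the cause, with log2 fold changes of the markers from -2.35 for Marco to -0.425, and this cannot be told apart from lower expression per cell because cells were not counted. A link to SRC-2 is the biological explanation that the design names, and with genotype the only recorded factor it stays a hypothesis.

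The second pattern is the fall of 9 of 16 immediate early transcripts. A large shift in the time of day at collection is argued against by the 19 circadian clock genes, whose median absolute log2 fold change was 0.128, although Bhlhe40, the largest at 0.591, was called lower, and a small shift stays open. A loss of macrophages that carried these transcripts may contribute, with a median of -0.618 over all 16 immediate early genes against -0.94 for the macrophage markers. Fos, Jun, Egr1 (named after its value was seen) and Gadd45g fell 7.14-fold, 3.99-fold, 3.77-fold and 2.92-fold, Fos further than every macrophage marker and the others further than each but Marco (5.10-fold, the next being Timd4 at 2.63-fold), which goes against such a loss as the whole cause for them, but they were picked for their large falls and do not decide it. Handling that differed between the groups could also lower such genes, 9 of 16 here, and it cannot be told apart from genotype, which stays open too, because handling per animal is not recorded in the labels.

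The third pattern is that 8 of 20 female-biased transcripts were lower and 6 of 14 male-biased transcripts higher in null liver. A male animal among the null samples is argued against by probe sets of the Y-linked genes Eif2s3y and Kdm5d, whose highest value on any array was 3.59, although no male liver was measured here to show the level these probe sets can reach. Xist, a transcript of the inactive X chromosome of females, argues against it too. Its probe sets read 10.33 to 10.43, 8.21 to 8.49 and 6.13 to 7.61 on the null arrays. On the wild-type arrays they read 10.12 to 10.50, 7.99 to 8.17 and 5.61 to 7.73. The array batch does not account for it, because each batch holds equal numbers of arrays of both genotypes. The mean of the female-biased list minus that of the male-biased list was -0.902 and -0.976 within the 2 batches. By medians the lists lay closer. The female-biased median was -0.206 within replicates 1 and 2 and -0.506 within replicate 3, and the male-biased median was 0.006 and -0.016. The difference of the means thus rests, for the male-biased list, on part of its members. An effect of genotype on sex-biased expression is a hypothesis that the design names, untested beyond the comparison itself.

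Of the 10 splits of the 6 arrays into groups of 3, 1 gave as many changed genes as the real one, the real split itself, and the same holds for the genes higher, lower and changed at least 1.5-fold and for the lists called. The real split gave 556, 184, 372 and 313 genes and 18 lists. The highest of the other splits gave 0, 0, 0 and 0 genes by limma and 10 lists, with up to 981 genes at an unadjusted p under 0.05 against 2041. The splits are too few for a share under 0.05. The 3 other splits that part all 3 pairs of equal replicate numbers differ from the real one by exchanging 1 pair, and gave 0 genes each and 3 to 6 lists. They gave 171, 122 and 225 genes at an unadjusted p under 0.05 in limma. In every split but the real one the genotype difference enters the spread within groups, which lowers the number of calls. The 0 genes are therefore no measure of the calls to be had without a difference. Each of the other splits still called between 1 and 10 lists, so lists can pass camera at the preset correlation where no gene passes. The groups of those splits mix the genotypes unequally, so part of the genotype difference stays between them. These list counts are therefore no rate of false list calls.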
